A study of Saccharomyces cerevisiae with 21 samples.

How the data were processed

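RNA from the budding yeast Saccharomyces cerevisiae, diploid strain BY4743, was measured on 21 Affymetrix yeast arrays of the type YG_S98. The strain carries deletions at the genes HIS3, LEU2 and URA3. Per the labels, cells grown in rich medium at 30 degrees C to an absorbance of 0.8 were resuspended in medium diluted 20-fold and dried in dishes of 15 ml at 22 to 25 degrees C, with 4 dishes pooled per sample. The 7 groups of 3 arrays were growing control cells, cells dried to 50% after 18 h, dry cells (42 h of drying and then 72 h at 20% relative humidity), and dry cells rehydrated for 15, 45, 90 or 360 min. The labels did not state whether the 3 replicates of a group were separate cultures, so every p-value given measures only the spread between these samples.

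The deposited table held linear probe-set signals, in the unit intensity. Per the labels, the authors read the images with the GeneChip Expression Analysis Software, applied a Wilcoxon signed rank test and combined the probes of a set with a linear mixed model in 2 steps. The software version, the scaling and the genome build were not given in the sources used here. The 2% trimmed mean lay between 500.2 and 500.5 on every array, so the arrays had been scaled to a common mean, while their medians ran from 140.6 to 205.7. The run records of the arrays, deposited beside the table and holding no measurement, placed them in 6 hybridization runs and on 3 scan days. No image or probe-level file was used here.

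Probe sets were assigned to genes with the platform's annotation and a RefSeq gene table. Of the 9335 probe sets, 60 were control sets and were left out of the tests. Among the 9275 tested, 6504 named 1 gene, 328 named several and 2443 named none. Together they covered 5656 genes, of which 5076 had a standard name. Signals were turned to log2(signal + 17.74), the added value being 10% of the median of all tested values (177.4). The range of the array medians was 46.3%, above the 5% set beforehand as the limit for keeping the deposited scaling, so the arrays were quantile normalized.

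The comparisons used limma 3.58.1 in R 4.3.3: a model of group means over all 21 arrays, with moderated variances and a trend on mean level (14 residual degrees of freedom, 4 prior degrees of freedom). A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change, and a moderated F test covered the 7 groups. For 33 gene lists with 962 named members, 886 of them measured, camera tested whether a list shifted against the other genes, two-sided, with an estimated correlation between genes, on the brightest probe set of each gene. Its p-values were adjusted over the 33 lists within each comparison. The groups, comparisons, lists, thresholds and the rule for named genes were fixed before the data were examined. That rule took, among called genes with a standard name whose 3 arrays of one group all lay above the 3 of the other, the 10 largest rises and the 10 largest falls in 50% dry against control, 15 min against dry, and 360 min against dry and against control, and the 5 largest each way in the other comparisons. It also took the 2 to 4 called members with the largest change from each list that passed its test or had at least 1/3 of its members called, and HIS3, LEU2 and URA3. Where a gene had several probe sets the brightest stood for it. Genes named outside the rule are said to be so.

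Alternatives recomputed the counts, lists and named genes, each where the alternative applies, with another added value (1% or 50% of the median), with the deposited scaling or median-centred arrays, without a fold minimum, without the trend, without the dimmest 20% of probe sets, with the replicate number as a block, with only the arrays compared, and without each array in turn. Lists were also tested with a preset correlation of 0.01 and with the mean of all probe sets of a gene. Chosen after seeing the data were a hybridization run block for the 4 groups that shared runs, the removal of probe sets with a within-group SD above 1, the F test without the 360 min group, and a count over 6291 probe sets of nuclear protein-coding genes. The calling procedure was tested on simulated data, where 36 to 48% of 2-fold changes and 76 to 92% of 3-fold changes were called in the right direction. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots drawn with matplotlib 3.10.9. The precision of each value is limited by the number of arrays, 3 per group.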

Results

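Transcript levels were compared along a course of drying and rehydration in yeast, on 21 arrays in 7 groups of 3: growing control cells, 50% dry cells, dry cells, and cells rehydrated for 15, 45, 90 and 360 min. Values are differences of log2 signal after quantile normalization, each with its standard error and with n = 3 arrays per group, unless stated otherwise. The standard errors rest on the spread of a probe set over all 21 arrays, so they can understate the spread in the groups compared. Array medians of the deposited signal averaged 171 ± 4.33 (SD) in control cells, 198 ± 6.76 in 50% dry cells, 203 ± 3.0 in dry cells and 143 ± 2.35 at 360 min. Replicate arrays correlated across probe sets at 0.984 to 0.992 in the other 6 groups and at 0.967 to 0.977 at 360 min. Of 9275 probe sets, 7652 (82.5%) differed among the 7 groups by the limma F test.

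**Figure D1:**
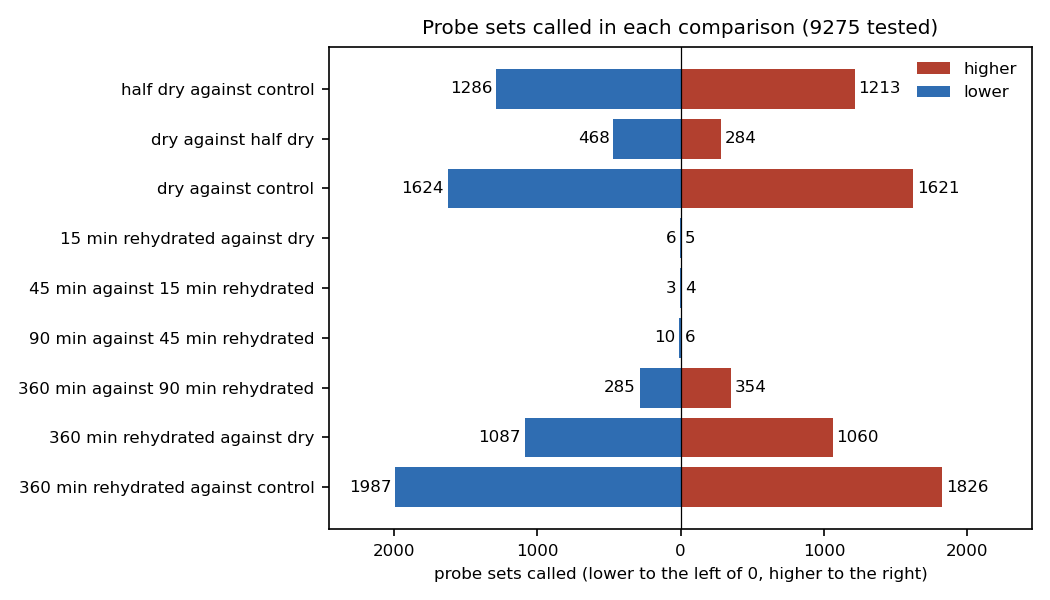
Probe sets called higher (right) or lower (left) in each of the 9 comparisons, out of 9275 tested, with 3 arrays per group. Between 7 and 16 were called in each step from dry cells to 90 min of rehydration.

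The comparison of 50% dry with control cells asks what changed between growth and the point at which cells were 50% dry. Per the labels, the dried cells had also been moved from rich to diluted medium and to a lower temperature, and kept there for hours. Water loss, medium, temperature and time therefore cannot be told apart in any comparison with control cells. The hydrophilin genes SIP18 and GRE1, whose small hydrophilic proteins are tied to water loss, rose by 7.65 ± 0.08 and by 6.32 ± 0.22. FDH1, for formate dehydrogenase, rose by 8.02 ± 0.11, SFC1, the mitochondrial succinate-fumarate carrier, by 6.70 ± 0.11, and SSA3, an Hsp70 chaperone, by 6.24 ± 0.20. MLS1 (malate synthase of the glyoxylate cycle) rose by 6.05 ± 0.17, PDH1 (propionate breakdown) by 6.01 ± 0.24, PUT4 (proline uptake) by 5.99 ± 0.11 and CIT3 (a mitochondrial citrate synthase) by 5.97 ± 0.18. RPL21A, a ribosomal protein gene, rose by 5.92 ± 0.54, but its signals on the 3 control arrays were 137.8, 0 and 0. The control levels of SIP18 and FDH1 (4.42 and 4.63) lay near the floor, so the added value sets the size of their rises: 9.70 and 9.63 with 1% of the median added, 5.57 and 6.08 with 50%. The adjusted p of these 10 genes lay between 1.91e-21 and 1.66e-08.

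Among the falls, YHB1, a flavohemoglobin, fell by 5.34 ± 0.19, ERG4, the last enzyme of ergosterol synthesis, by 5.07 ± 0.16, and HIS1, the entry enzyme of histidine synthesis, by 5.05 ± 0.16. The polyamine transporter gene TPO2 fell by 4.84 ± 0.24, ASN1 (asparagine synthetase) fell by 4.78 ± 0.24, GND1 (pentose phosphate pathway) fell by 4.69 ± 0.14 and HXT4 (hexose transport) by 4.33 ± 0.32. The aldehyde reductase gene ARI1 fell by 4.27 ± 0.17, PHO5 (acid phosphatase) by 4.24 ± 0.11 and SUN4 (cell wall) fell by 4.17 ± 0.17. All 20 genes had their 3 arrays of one group above the 3 of the other, and the adjusted p of these 10 lay between 1.53e-16 and 7.43e-10.

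Lists for growth on fat and on carbon sources other than sugar shifted up. Of 21 genes of fatty acid oxidation and the peroxisome, 20 rose, none fell and 1 did neither, with a median of 4.07 and an adjusted p of 4.3e-05; the catalase gene CTA1 rose by 5.69 ± 0.08 and the carnitine acetyltransferase gene YAT2 by 5.46 ± 0.22. Of 18 genes of gluconeogenesis and the glyoxylate cycle, 14 rose and 4 did neither (median 3.99, adjusted p = 0.00108), among them FBP1, for fructose-1,6-bisphosphatase, by 5.76 ± 0.13 and ADY2, for acetate uptake, by 5.23 ± 0.10. Of 16 stationary phase genes, 14 rose and 2 did neither (median 2.27, adjusted p = 0.00108), including SPG1 by 5.45 ± 0.14 and HBT1 by 4.75 ± 0.11. Of 16 genes of the TCA cycle, 6 rose and 10 did neither (median 0.75, adjusted p = 0.0285), with SDH3, a succinate dehydrogenase subunit, up by 2.14 ± 0.17.

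Other lists also shifted up. Of 23 genes of autophagy and vacuolar proteases, 11 rose, 1 fell and 11 did neither (median 0.87, adjusted p = 0.00746); ATG1, the kinase that starts autophagy, rose by 1.88 ± 0.12, and the aminopeptidase gene APE1 fell by 1.87 ± 0.13. Of 23 genes for the use of nitrogen sources, 9 rose, 1 fell and 13 did neither (median 0.75, adjusted p = 0.0285), with the ammonium permease gene MEP2 up by 2.96 ± 0.09. Of 36 nuclear genes of the respiratory chain and ATP synthase, 7 rose, 3 fell and 26 did neither (median 0.48, adjusted p = 0.0285). This list, here and below, holds no gene of the mitochondrial genome. NDE2, for an NADH dehydrogenase, rose by 5.08 ± 0.14 and CYC1, for cytochrome c, fell by 3.14 ± 0.15.

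Lists of protein and sterol synthesis shifted down. Of 45 tRNA synthetase and translation factor genes, 34 fell, none rose and 11 did neither (median -1.42, adjusted p = 0.00108); the synthetase genes THS1 and KRS1 fell by 3.29 ± 0.19 and by 3.13 ± 0.10. Of 48 genes of amino acid synthesis, 25 fell, 3 rose and 20 did neither (median -1.19, adjusted p = 0.00022), with ARO8, an aromatic aminotransferase, down by 3.66 ± 0.13 and ARG3, of arginine synthesis, up by 3.31 ± 0.17. Of 23 ergosterol genes, 13 fell and 10 did neither (median -1.18, adjusted p = 0.00929), including ERG26, which fell by 3.57 ± 0.18. Of 15 genes of folding in the endoplasmic reticulum, 7 fell and 8 did neither (median -0.89, adjusted p = 0.0285), and of 67 mitochondrial ribosomal protein genes 12 fell, 1 rose and 54 did neither (median -0.53, adjusted p = 0.0321). Of 80 cytosolic ribosomal protein genes, 46 fell, 11 rose and 23 did neither (median -1.09), with an adjusted p = 0.178 with an estimated correlation.

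Among the 16 genes of glycolysis and ethanol fermentation, 6 rose, 3 fell and 7 did neither (median 0.15 and mean 0.90, while the test pointed down, adjusted p = 0.959). Those with the largest rises were read by probe sets that varied on the control arrays. ENO1 and ENO2, for enolase, rose by 5.53 ± 0.54 and by 4.39 ± 0.75, while their control signals averaged 183 and 264; a probe set shared by the pair averaged 2738 in control and 6307 in 50% dry cells. Of 16 genes of hexose transport, 4 rose, 5 fell and 7 did neither (median 0.18 but mean -0.32, adjusted p = 0.84), with HXT5 up by 4.60 ± 0.22 and HXT3 and HXT1 down, falling by 3.78 ± 0.20 and by 3.40 ± 0.13. Of the 6 hydrophilins, 3 rose, 1 fell and 2 did neither (median 0.50, adjusted p = 0.311), the fall being that of HSP12, by 1.10 ± 0.41, and it ended with the deposited scaling (-0.79, adjusted p = 0.123). Of 24 chaperone genes, 3 rose, 5 fell and 16 did neither, and of 16 genes of trehalose and glycogen metabolism 2 rose, 4 fell and 10 did neither, with the trehalase gene ATH1 up by 2.69 ± 0.08 and the trehalose synthase subunit gene TPS3 down, falling by 1.74 ± 0.11.

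In all, 1213 probe sets were higher and 1286 lower in 50% dry than in control cells (48.5% higher), against 1354 and 1112 as deposited (54.9%) and 1044 and 1449 with median-centred arrays (41.9%), and 12 of 33 lists shifted. Adjusted over the list alone, the numbers of members that rose or fell were the same in each list named above. The 3' minus 5' signal difference of ACT1, a sign of RNA quality, went from -0.57 ± 0.33 (SD) in control cells to 0.76 ± 0.26 in 50% dry cells, while those of SRB4 and SPT15 differed by 0.38 and 0.16 (adjusted p of 0.0436 and 0.521). With the deposited scaling 5 of the 12 list calls held and with median-centred arrays 4, those of fatty acid oxidation, translation factors, ergosterol and amino acid synthesis under both. Lists that missed the threshold under both had medians of 3.83 and 3.63 (gluconeogenesis), 2.10 and 1.91 (stationary phase), 0.65 and 0.45 (TCA cycle), 0.87 and 0.67 (nitrogen sources), 0.35 and 0.15 (respiratory chain), -0.67 and -0.86 (folding) and -0.45 and -0.65 (mitochondrial ribosome), with adjusted p from 0.0625 to 0.594; autophagy missed it when centred (0.68, adjusted p = 0.0941). The control arrays were hybridized in a run and scanned on a day of their own, so run, day and group cannot be told apart in any comparison with control cells.

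**Figure D2:**
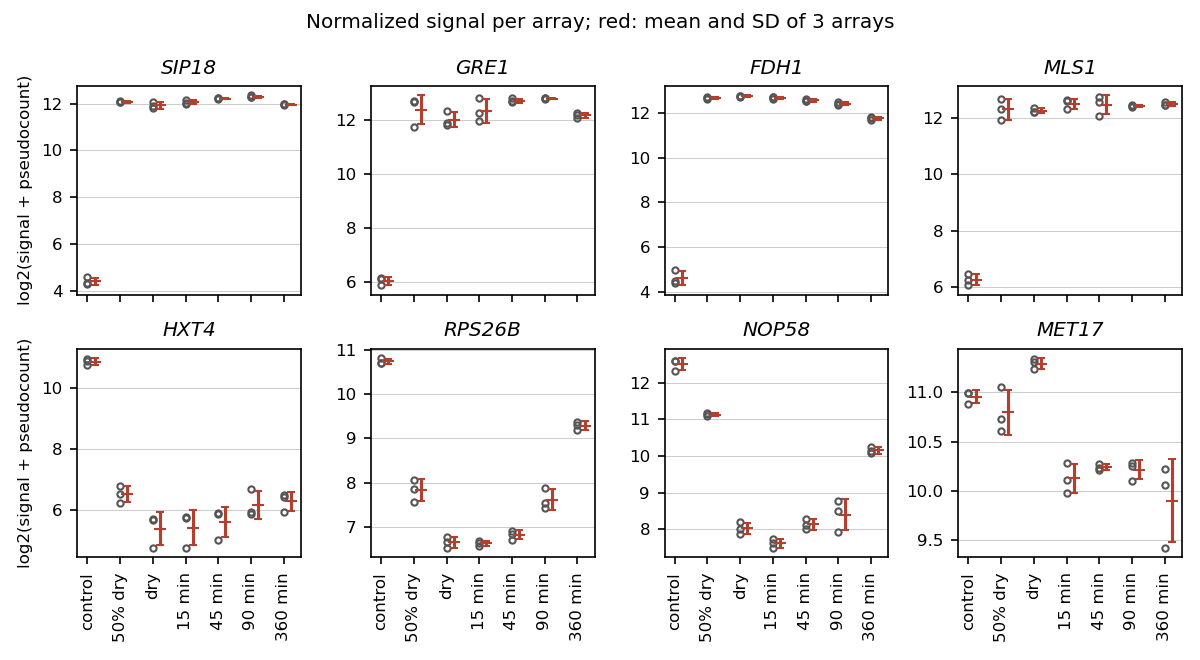
Normalized log2 signal of 8 genes on each of the 21 arrays by group, with the mean and SD of 3 arrays in red. SIP18 stood at 4.42 in control cells and at 12.08 in 50% dry cells, and RPS26B rose from 7.61 at 90 min to 9.29 at 360 min.

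The step from 50% dry to dry cells asks what changed late in drying or in dry storage. Per the labels, dry cells had 42 h of drying and then 72 h at 20% relative humidity, against 18 h of drying. Late drying and storage therefore cannot be told apart in this step. Lists for making ribosomes shifted down. Of 89 ribosome biogenesis genes, 35 fell, 2 rose and 52 did neither (median -0.78, adjusted p = 1.81e-07); NOP58, of the particles that modify ribosomal RNA, fell by 3.11 ± 0.15, NSR1 by 2.91 ± 0.17 and NOP1 by 2.26 ± 0.10. Of 80 cytosolic ribosomal protein genes, 46 fell, none rose and 34 did neither (median -1.08, adjusted p = 0.025), led by RPL22B, which fell by 3.30 ± 0.15. Of 23 subunits of RNA polymerases I and III, 7 fell and 16 did neither (median -0.53, adjusted p = 0.025), with RPA49 down, falling by 2.39 ± 0.21. Of 45 translation genes, 6 fell and 39 did neither (median -0.50, adjusted p = 0.0242), among them FRS1 by 2.05 ± 0.19. Of 48 amino acid synthesis genes, 10 fell and 38 did neither (median -0.31, adjusted p = 0.00588), among them SER2 by 2.24 ± 0.28. With 1% and 50% of the median added SER2 gave -3.35 and -1.04.

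Smaller lists moved in the same step. Of 16 hexose transport genes, 4 fell and 12 did neither (median -0.34, adjusted p = 0.0447), with HXT2 down, falling by 2.39 ± 0.19. Of 16 TCA cycle genes, 4 fell and 12 did neither (median -0.27, adjusted p = 0.025), including IDH2, which fell by 1.28 ± 0.14. Of 15 genes of the phosphate response, 3 rose and 12 did neither (median 0.55, adjusted p = 0.0242), with SPL2 up by 1.54 ± 0.18. The autophagy list shifted up (median 0.36, adjusted p = 0.0363) with 1 of 23 genes called, ATG14 by 1.13 ± 0.10, and the proteasome list (median 0.25, adjusted p = 0.0385) with none of 32. Of 23 genes of iron and copper uptake, 4 rose, 4 fell and 15 did neither (median 0.03, mean -0.13, adjusted p = 0.958); the copper transporter gene CTR1 fell by 2.87 ± 0.19.

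The largest rises were those of RDN25-1, for 25S ribosomal RNA, by 5.21 ± 0.74, TIP1, a cell wall mannoprotein gene, by 3.78 ± 0.39, and a U5 small nuclear RNA probe set annotated as SNR7-L, by 3.77 ± 0.11. The RDN25-1 probe set had an SD of 1.32 among dry arrays, and its rise was 3.68 with the hybridization run as a block. PDR12, which exports weak acids, rose by 3.69 ± 0.10 and SUF16, a glycine tRNA gene, by 3.60 ± 0.23. SUF16 stood near the floor in 50% dry cells (4.51), so the added value sets this size: 5.28 with 1% of the median added and 1.89 with 50%. Besides RPL22B and NOP58, the largest falls were those of REE1 by 3.27 ± 0.12, the arginine transporter gene ALP1 by 2.98 ± 0.16 and the acid phosphatase gene PHO3 by 2.93 ± 0.27. In total 284 probe sets were higher and 468 lower, and adjusted over the list alone the counts in these lists were the same. ACT1 had a 3' minus 5' difference of 0.94 ± 0.03 (SD) in dry cells, and that of SPT15 went from 1.64 ± 0.20 to 1.05 ± 0.66.

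Only 1 array of dry cells shared a run with the 3 of 50% dry cells; against them it gave ribosomal protein genes a median of -1.07 and ribosome biogenesis genes one of -0.81. The run as a block over the 4 groups that share runs rests on the same 1 dry array; with it 736 probe sets were called, and the lists of hexose transport, TCA cycle, proteasome and autophagy kept medians of -0.30, -0.31, 0.24 and 0.37 but missed the threshold (adjusted p of 0.104, 0.102, 0.102 and 0.102). In the same 4 groups without the block, hexose transport, TCA cycle and autophagy missed it too (0.0791, 0.0547 and 0.0679). Only ribosome biogenesis, amino acid synthesis and phosphate response passed under all 3 scalings; as deposited, ribosomal proteins, polymerase subunits and translation had medians of -0.97, -0.55 and -0.43 (adjusted p of 0.0737, 0.087 and 0.117). Adding 50% of the median instead of 10% lowered the count to 410 and ended the call of ATG14 (0.79).

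Dry cells were also compared with control cells, which covers the whole of the drying together with the changes of medium, temperature and time. It also covers the 72 h at 20% relative humidity. FDH1 was higher by 8.11 ± 0.11, SIP18 by 7.50 ± 0.08, SSA3 by 6.89 ± 0.20, SFC1 by 6.78 ± 0.11 and MLS1 by 6.01 ± 0.17. HXT4 fell by 5.47 ± 0.32, TPO2 by 5.43 ± 0.24, ERG4 by 5.37 ± 0.16, SUN4 by 5.30 ± 0.17 and TKL1, for transketolase, by 5.29 ± 0.19. With 1% and 50% of the median added FDH1 gave 9.72 and 6.17, SIP18 9.54 and 5.42, and HXT4 -6.24 and -4.08. The adjusted p of these 10 genes lay between 2.75e-21 and 1.61e-11. Probe sets higher numbered 1621 and lower 1624 (50.0% higher), against 1826 and 1440 as deposited (55.9%) and 1388 and 1801 with median-centred arrays (43.5%). The 3' minus 5' difference was above that of control cells by 1.51 for ACT1 (adjusted p = 1.12e-08) and by 0.61 for SRB4 (adjusted p = 0.0025), while that of SPT15 differed by -0.43 (adjusted p = 0.0821).

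All 16 stationary phase genes rose (median 2.36, adjusted p = 0.00184), as did 20 of 21 genes of fatty acid oxidation, where 1 fell (median 3.68, adjusted p = 9.54e-05), 14 of 18 of gluconeogenesis, where 4 did neither (median 3.85, adjusted p = 0.00214), and 15 of 23 of autophagy, where 1 fell and 7 did neither (median 1.16, adjusted p = 0.00351). Examples were HBT1 by 4.80 ± 0.11, CRC1, the carnitine carrier gene, by 5.40 ± 0.12, and ATG9 by 2.61 ± 0.16. Of 80 cytosolic ribosomal protein genes, 64 fell, 6 rose and 10 did neither (median -2.30, adjusted p = 0.047). RPL13A fell by 4.74 ± 0.17 and RPS26B by 4.09 ± 0.13. Probe sets of RPL21A, RPL21B and RPS21B varied strongly among the control arrays, so rises of such genes are uncertain. Of 45 translation genes, 38 fell and 7 did neither (median -1.86, adjusted p = 0.00074), and of 48 amino acid synthesis genes 32 fell, 3 rose and 13 did neither (median -1.79, adjusted p = 9.54e-05). Of 89 ribosome biogenesis genes, 37 fell, 4 rose and 48 did neither (median -0.77, adjusted p = 0.000455), and of 23 ergosterol genes 15 fell, 1 rose and 7 did neither (median -1.29, adjusted p = 0.00621).

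Of 34 cell cycle regulators, 15 fell, 1 rose and 18 did neither (median -0.87, adjusted p = 0.047), with the G1 cyclin genes CLN2 and CLN3 lower (-3.18 ± 0.24 and -2.68 ± 0.12); CLN2 gave -5.07 with 1% of the median added and -1.52 with 50%. Subunits of RNA polymerases I and III (10 of 23 fell, 2 rose and 11 did neither, median -0.64) and folding in the endoplasmic reticulum (6 of 15 fell, 1 rose and 8 did neither, median -0.94) each had an adjusted p of 0.047. The nitrogen source list (10 of 23 rose, 1 fell, 12 neither) had a median of 0.72 and an adjusted p = 0.0513 with an estimated correlation, and of 16 hexose transport genes 8 fell, 3 rose and 5 did neither (median -1.03, adjusted p = 0.203). Adjusted over the list alone, each of these counts was the same. With the deposited scaling 5 of the 12 list calls held and with median-centred arrays 5, those of fatty acid oxidation, translation factors, ergosterol and amino acid synthesis under both. Lists that missed the threshold under both had medians of 3.47 and 3.25 (gluconeogenesis), 2.25 and 2.02 (stationary phase), -2.14 and -2.37 (ribosomal proteins), -0.67 and -0.90 (cell cycle), -0.53 and -0.76 (polymerases I and III) and -0.78 and -1.01 (folding), with adjusted p from 0.0698 to 0.197. Ribosome biogenesis missed it as deposited (-0.62, adjusted p = 0.0884) and autophagy when centred (1.05, adjusted p = 0.0698). The lists of ribosomal proteins and of folding also missed the threshold with the mean of all probe sets per gene (adjusted p = 0.0548 for each).

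**Figure D3:**
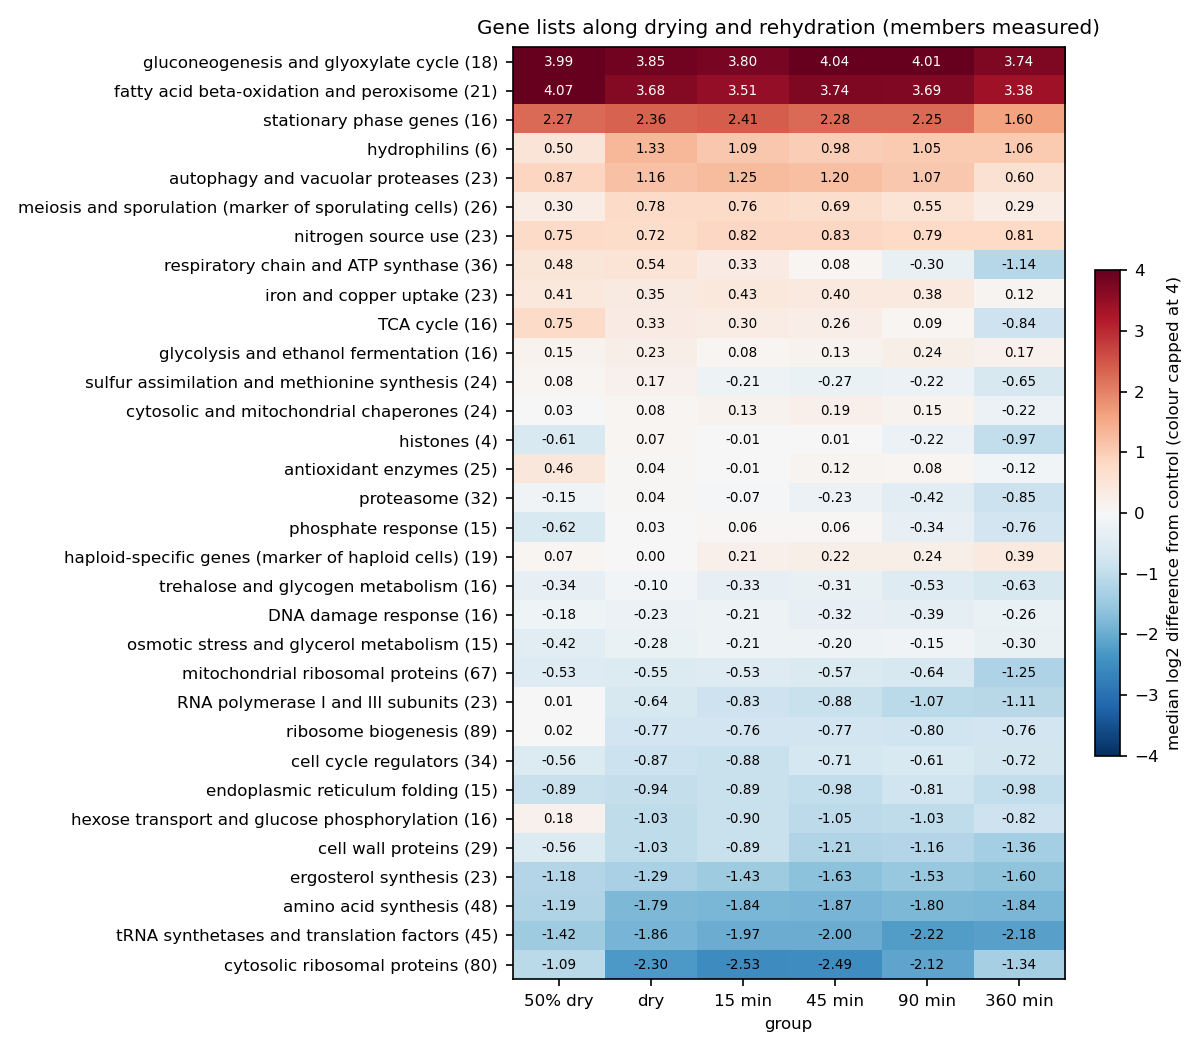
Median log2 difference from control cells of the measured members of 32 gene lists (number in brackets) in each of the other 6 groups, with colour capped at 4. Cytosolic ribosomal proteins went from -1.09 in 50% dry cells to -2.30 in dry cells and -1.34 at 360 min, and fatty acid oxidation stayed between 3.38 and 4.07.

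Cells rehydrated for 15 min were compared with dry cells to find early changes on wetting. MET17, an enzyme of sulfur assimilation, fell by 1.16 ± 0.15 (adjusted p = 0.000739), and SEO1, a putative permease gene, fell by 1.77 ± 0.24 (adjusted p = 0.000989). The sulfur assimilation and methionine list shifted down (median -0.28, adjusted p = 3.19e-05), with 1 of 24 genes called. Ribosomal protein genes (median -0.32, adjusted p = 0.0394), ribosome biogenesis (-0.10, adjusted p = 0.000995), the respiratory chain (-0.17, adjusted p = 8.1e-05), the proteasome (-0.15, adjusted p = 0.0176) and the TCA cycle (-0.14, adjusted p = 0.0342) shifted down with none of their 80, 89, 36, 32 and 16 genes called, over all genes or adjusted over the list alone. With median-centred arrays MET17 changed by less than 2-fold (-0.91), and the respiratory chain, the TCA cycle, the proteasome and ribosomal proteins had medians of 0, 0.11, -0.02 and -0.22. The 3' minus 5' difference of ACT1 went from 0.94 ± 0.03 (SD) to 1.28 ± 0.09 in the same step.

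In total 5 probe sets were higher and 6 lower at 15 min, and 1140 had an unadjusted p under 0.05. The other called genes, chosen after their values were seen, were SNR67, a small nucleolar RNA gene, up by 1.2 ± 0.23, FLC3, of FAD transport, which fell by 1.10 ± 0.20, and YKL068W-A, which fell by 1.09 ± 0.25. With the deposited scaling 5 were higher and 13 lower (27.8% higher, against 45.5%), and the sulfur list alone kept its call under all 3 scalings. Within the run shared by 2 arrays of each group 4 were called, the sulfur list had a median of -0.33 and ribosomal proteins one of -0.32; with the run as a block, which rests on the same 4 arrays, 2 were called, against 12 in the same 4 groups without it. With the block SEO1 (-1.72, adjusted p = 0.0537) and the lists of the TCA cycle (median -0.17, adjusted p = 0.124) and the proteasome (median -0.17, adjusted p = 0.0884) kept the size of their changes but missed the threshold, as the TCA cycle did without it (0.0582).

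Between 15 and 45 min of rehydration, the genes of the respiratory chain and ATP synthase shifted down (median -0.13, adjusted p = 0.0149), with none of 36 called over all genes or adjusted over the list alone. In the same step the 3' minus 5' difference went from 1.28 to 1.79 for ACT1, from 2.05 to 2.38 for SRB4 and from 1.59 to 2 for SPT15. Among all probe sets 4 were higher and 3 lower, and 1176 had an unadjusted p under 0.05. Chosen after their values were seen, the named ones were COB, for mitochondrial cytochrome b, up by 1.26 ± 0.26 in 1 of its probe sets, ESC1, of telomere silencing, which fell by 1.06 ± 0.23, FAS1, for fatty acid synthase, which fell by 1.01 ± 0.23, and YHR050W-A, which fell by 1.01 ± 0.18.

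The list call ended under both other scalings (median -0.11 as deposited and -0.01 when centred), where 3 probe sets were higher and 6 lower as deposited (33.3% higher, against 57.1%). The count ran from 1 without replicate 3 at 15 min or replicate 1 at 45 min, through 2 and 3 without replicates 3 and 2 at 45 min, to 15 without replicate 2 at 15 min. With the run as a block 64 were called, against 0 in the same 4 groups without it, and 66 within the only shared run; both rest on 1 array at 15 min. The list had a median of -0.14 and an adjusted p of 0.617 with the block and of 0.102 without.

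Between 45 and 90 min, DED1, an RNA helicase of translation initiation, fell by 1.2 ± 0.13 and MET13, of methionine synthesis, fell by 1.14 ± 0.12 (adjusted p = 2.67e-05 each). CPD1, for a cyclic phosphodiesterase, fell by 1.10 ± 0.20 and CDC6, needed to start DNA replication, by 1.06 ± 0.24, while the cyclin gene CLN2 rose by 1.04 ± 0.24 (adjusted p = 0.00388, 0.0192 and 0.018). The respiratory chain shifted down again (median -0.23, adjusted p = 0.000774) with none of 36 called, and adjusted over the list alone none either. The 3' minus 5' difference of ACT1 went from 1.79 to 2.24 and the spiked hybridization controls from 10.04 to 10.65 in the same step. Ribosomal protein genes had a median of 0.31 with none of 80 called.

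In total 6 probe sets were higher and 10 lower, and 1699 had an unadjusted p under 0.05; median-centred arrays gave 10 and 10 (50.0% higher, against 37.5%) and an adjusted p of 0.146 for the respiratory chain. Without replicate 1 at 90 min 30 were called, and with only the 6 arrays compared CLN2, CPD1 and CDC6 missed the threshold (adjusted p of 0.0604, 0.0536 and 0.0534); CDC6 also changed by less than 2-fold as deposited (-0.96) and when centred (-0.94), and all 3 did with 50% of the median added (0.34, -0.83 and -0.38). The groups were scanned on different days and in different runs, so day and time of rehydration cannot be told apart.

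The step from 90 to 360 min asks what changed once cells had been wet for hours. Of 80 cytosolic ribosomal protein genes, 14 rose, none fell and 66 did neither (median 0.74, adjusted p = 0.0348), with RPS26B up by 1.68 ± 0.13 and RPL22A by 1.41 ± 0.24. Of 36 respiratory chain genes, 9 fell and 27 did neither (median -0.61, adjusted p = 0.00122), with the cytochrome oxidase subunit genes COX9 and COX5A lower (-1.94 ± 0.19 and -1.66 ± 0.10). Of 16 TCA cycle genes, 3 fell and 13 did neither (median -0.54, adjusted p = 0.0457), with SDH2 lower (-1.5 ± 0.15). Of 32 proteasome genes, 2 fell and 30 did neither (median -0.48, adjusted p = 0.00706), the base subunit RPN1 by 1.23 ± 0.08.

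Ribosome biogenesis (median 0.06, adjusted p = 0.0348; 4 of 89 higher, 2 lower and 83 neither) and amino acid synthesis (median 0.10, adjusted p = 0.0457; 1 of 48 higher, 2 lower and 45 neither) shifted up, NOP58 by 1.75 ± 0.15 and HIS1 by 1.68 ± 0.16; with the deposited scaling the first had a median of -0.09. Of the 4 histone genes measured, HTB2 rose by 1.05 ± 0.10 and HTB1 fell by 1.09 ± 0.14. Adjusted over the list alone, each count was the same. Of single genes the stress gene HOR7 rose by 3.96 ± 1.22, TDH3, for the glycolytic glyceraldehyde-3-phosphate dehydrogenase, by 3.80 ± 1.42, the cell wall gene CCW12 by 3.45 ± 0.91 and SCEI, an endonuclease gene of a mitochondrial intron, by 2.22 ± 0.36. The within-group SD at 90 min was 1.33 for HOR7, 2.63 for TDH3 and 2.37 for CCW12. A probe set of the Hsp70 gene SSA1 was higher by 8.09 ± 0.72, from near the floor at 90 min. Sets shared with SSA2 disagreed: a shared set went from 2910 to 19400, while another averaged 1683 at 360 min and 2379 in 50% dry cells. The largest falls were those of NGK1 (-2.48 ± 0.13), CDC39, the scaffold of the CCR4-NOT deadenylase (-2.16 ± 0.17), SNT309, of the spliceosome (-2.12 ± 0.21), NDC80, of the kinetochore (-2.08 ± 0.34), and SWP82, of the SWI/SNF complex (-2.07 ± 0.22); with 1% and 50% of the median added NGK1 gave -3.96 and -1.12.

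Over this step the spiked hybridization controls went from 10.65 ± 0.14 (SD) to 12.16 ± 0.32, and the 3' minus 5' difference of ACT1 from 2.24 ± 0.24 to 2.71 ± 0.17 and that of SPT15 from 2.18 ± 0.09 to 2.74 ± 0.28, while that of SRB4 went from 2.65 ± 0.26 to 2.36 ± 0.02. The groups shared a scan day but were hybridized in separate runs, so run and time cannot be told apart. In total 354 probe sets were higher and 285 lower (55.4% higher), against 385 and 521 as deposited (42.5%) and 790 and 216 with median-centred arrays (78.5%). The proteasome list alone kept its call under all 3 scalings. Ribosomal proteins missed the threshold as deposited (0.71, adjusted p = 0.0581) and when centred (0.93, adjusted p = 0.0664), as did the TCA cycle (-0.62 and -0.39, adjusted p of 0.236 and 0.37), and the respiratory chain when centred (-0.63, adjusted p = 0.147). HTB2 rose by less than 2-fold as deposited (0.83). Over probe sets of nuclear protein-coding genes 129 were higher and 261 lower. With 1% of the median added, HOR7 and TDH3 missed the threshold (adjusted p of 0.0939 and 0.172), and with 50% added SNT309 fell by less than 2-fold (-0.97).

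Cells at 360 min were compared with dry cells to cover the whole of rehydration. Lists of respiration shifted down: of 36 nuclear genes of the respiratory chain and ATP synthase 20 fell, none rose and 16 did neither (median -1.23, adjusted p = 0.000261). Among them were RIP1, the Rieske iron-sulfur protein gene (-3.19 ± 0.11), COX5A (-2.79 ± 0.10), QCR10 (-2.70 ± 0.13) and ATP3 (-2.52 ± 0.09). The list holds no gene of the mitochondrial genome, where 21 of 28 probe sets rose (median 1.88). Of 16 TCA cycle genes, 8 fell and 8 did neither (median -0.93, adjusted p = 0.0283), including SDH2 (-2.12 ± 0.15) and ACO1, for aconitase (-1.86 ± 0.12). Of 32 proteasome genes, 14 fell and 18 did neither (median -0.93, adjusted p = 0.00349), with RPN12 lower (-2.32 ± 0.17). Adjusted over the list alone, these counts were the same.

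Other lists held called genes without passing their test. Of 80 cytosolic ribosomal protein genes, 24 rose, none fell and 56 did neither (median 0.68), with an adjusted p = 0.174 with an estimated correlation. Of 16 stationary phase genes, 7 fell and 9 did neither (median -0.74, adjusted p = 0.176), with XBP1, a repressor gene, down, falling by 1.77 ± 0.16. Of 23 ergosterol genes, 6 rose, 4 fell and 13 did neither (median 0.19, adjusted p = 0.3); ERG6 rose by 1.68 ± 0.15 and ERG1, for squalene epoxidase, fell by 2.41 ± 0.36. Of 15 genes of osmotic stress and glycerol metabolism, 1 rose, 4 fell and 10 did neither (median -0.22, mean 0.16, adjusted p = 0.815), including GPD1, of glycerol synthesis, which fell by 1.61 ± 0.13, or by 0.85 with median-centred arrays. Of 16 genes of the DNA damage response, 1 rose, 5 fell and 10 did neither (median -0.56, adjusted p = 0.369), including the checkpoint kinase gene RAD53, which fell by 1.85 ± 0.14.

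Among single genes, HOR7 rose by 7.57 ± 1.22, TDH3 by 5.18 ± 1.42, the stress gene DDR2 by 4.66 ± 1.78 and CCW12 by 4.14 ± 0.91; their probe sets had within-group SDs in dry cells of 1.76, 3.28, 3.02 and 0.89. A probe set of SSA1 was higher by 8.43 ± 0.72, but it stood at the floor (4.16) on all dry arrays, so the added value sets this size: 11.68 with 1% of the median added and 6.14 with 50%. Sets that SSA1 shares with SSA2 disagreed. A shared set went from 2032 in dry cells to 19400 at 360 min, while another averaged 2379 in 50% dry cells and 1683 at 360 min. These sets do not settle whether SSA1 rose. The U3 small nucleolar RNA gene SNR17A rose by 2.98 ± 0.12, SCEI by 2.97 ± 0.36, HMS2 by 2.89 ± 0.28, CLN2 by 2.75 ± 0.24 and COB by 2.74 ± 0.21. With 1% and 50% of the median added CLN2, near the floor in dry cells (4.42), gave 4.60 and 1.22. NGK1, near it at 360 min (4.60), gave -5.39 and -2.10, HOR7 gave 9.58 and 5.88, and TDH3 gave 6.31 and 4.23. NGK1 fell by 3.80 ± 0.13, CDC39 by 3.26 ± 0.17, SEO1 by 3.02 ± 0.24, GAC1, a phosphatase subunit gene of glycogen synthesis, by 2.98 ± 0.07 and MOH1 by 2.97 ± 0.45. Also lower were PET20 (-2.93 ± 0.09), SDH8, an assembly factor of succinate dehydrogenase (-2.88 ± 0.10), ECM13 (-2.86 ± 0.12) and UBC6, a ubiquitin-conjugating enzyme of the endoplasmic reticulum (-2.84 ± 0.21).

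In total 1060 probe sets were higher and 1087 lower (49.4% higher), against 866 and 1717 as deposited (33.5%), where the median of all probe sets was -0.20, and 1711 and 750 with median-centred arrays (69.5%). The TCA cycle list missed the threshold under both (medians of -0.97 and -0.51, adjusted p of 0.327 and 0.524), the proteasome as deposited (-1.15, adjusted p = 0.0696) and the respiratory chain when centred (-0.93, adjusted p = 0.179). With 1% of the median added DDR2 had an adjusted p of 0.0515. The 3' minus 5' difference of ACT1 went from 0.94 ± 0.03 (SD) in dry cells to 2.71 ± 0.17 at 360 min and that of SRB4 from 1.61 ± 0.31 to 2.36 ± 0.02, and spiked hybridization controls rose from 9.82 ± 0.21 to 12.16 ± 0.32 on the log2 scale. The groups were scanned on different days, so day and rehydration cannot be told apart.

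**Figure D4:**
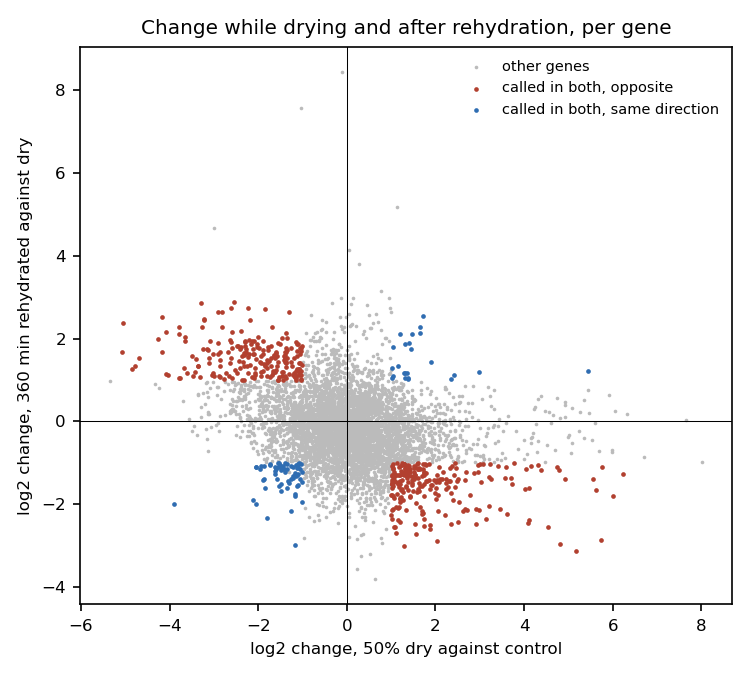
Log2 change from control to 50% dry cells (x) and from dry cells to 360 min of rehydration (y), 1 point per gene for 5656 genes. Red points (440 genes) were called in both in opposite directions and blue points (89) in the same direction.

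Whether genes that moved while drying moved back after rehydration was asked from the changes of 50% dry against control and of 360 min against dry, which share no arrays. Across 5656 genes, which are not independent replicates, the changes correlated at r = -0.30 and rho = -0.28. Of the called genes, 230 rose and then fell, where independent lists would share 141.6, and 210 fell and then rose, where they would share 79.5. The Hsp70 gene SSA3 rose by 6.24 ± 0.20 and then fell by 1.26 ± 0.20. IDH1, of the TCA cycle, rose by 1.62 ± 0.18 and then fell by 1.48 ± 0.18. But IDH1 had already fallen by 1.25 from 50% dry to dry cells, so much of its rise was gone before rehydration. The fall of SSA3 was 0.37 with median-centred arrays (adjusted p = 0.0938) and 0.84 as deposited. Called in the same direction were 89 genes, 24 higher in both and 65 lower in both, against 80 and 140.7 of independent lists. As deposited 455 genes were called in opposite directions and 153 in the same, and with median-centred arrays 406 and 129, with r = -0.21 under both.

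Cells at 360 min, which had also been through the change of medium and temperature, were compared with control cells to find what had not returned. SIP18 was still higher by 7.54 ± 0.08, FDH1 by 7.13 ± 0.11, MLS1 by 6.24 ± 0.17, GRE1 by 6.12 ± 0.22, SFC1 by 5.92 ± 0.11 and SSA3 by 5.63 ± 0.20. With 1% and 50% of the median added SIP18 gave 9.58 and 5.45 and FDH1 8.74 and 5.21. Of 21 genes of fatty acid oxidation, 18 were higher, 1 lower and 2 neither (median 3.38, adjusted p = 0.000148), of 18 of gluconeogenesis 15 were higher and 3 neither (median 3.74, adjusted p = 0.00144), and of 16 stationary phase genes 11 were higher and 5 neither (median 1.60, adjusted p = 0.00525). Examples were POX1, for acyl-CoA oxidase, by 5.48 ± 0.15, PCK1, for the gluconeogenic carboxykinase, by 5.02 ± 0.08, and SPG4 by 3.78 ± 0.10. Of 23 autophagy genes, 8 were higher, 1 lower and 14 neither (median 0.60, adjusted p = 0.0236).

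Other lists were lower. Of 45 translation genes, 37 were lower and 8 neither (median -2.18, adjusted p = 0.00157), of 48 amino acid synthesis genes 37 were lower, 3 higher and 8 neither (median -1.84, adjusted p = 0.000231), and of 89 ribosome biogenesis genes 38 were lower, 5 higher and 46 neither (median -0.76, adjusted p = 0.00144). Of 67 mitochondrial ribosomal protein genes, 38 were lower, 3 higher and 26 neither (median -1.25, adjusted p = 0.0236). Of 36 nuclear respiratory chain genes, 19 were lower, 2 higher and 15 neither (median -1.14, adjusted p = 0.0236). Of 23 ergosterol genes, 14 were lower, 1 higher and 8 neither (median -1.60, adjusted p = 0.0137), and of 32 proteasome genes 14 were lower and 18 neither (median -0.85, adjusted p = 0.0314). With the mean of all probe sets per gene the proteasome had an adjusted p of 0.0506. Examples were MES1, which fell by 3.10 ± 0.20, ARO4 by 3.15 ± 0.20, MRPS8 by 3.10 ± 0.16, ERG26 by 4.07 ± 0.18 and PRE1 by 1.70 ± 0.11. MRPS8 gave -3.95 with 1% of the median added and -1.78 with 50%. Of 80 cytosolic ribosomal protein genes, 53 were lower, 10 higher and 17 neither (median -1.34), with an adjusted p = 0.186 with an estimated correlation. Among the 10 higher was RPL21A (5.04), whose probe set varied strongly among the control arrays. Probe sets of RPL21B and RPS21B varied strongly there too. Of 16 TCA cycle genes, 5 were lower, 1 higher and 10 neither (median -0.84, adjusted p = 0.12).

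Of single genes, TDH3 was higher by 7.36 ± 1.42 and SSA1 by 7.33 ± 0.72, with control signals that averaged only 46 and 51. A probe set that SSA1 shares with SSA2 went the other way, from 4257 in control cells to 1683 at 360 min. Another shared set, unsteady on the control arrays, went from 51 to 19400. A set that TDH3 shares with TDH2 went from 5498 to 18819. SNR7-L was higher by 6.20 ± 0.11 and ATP6, a mitochondrial gene, by 5.82 ± 0.37. Lower were SFK1 (-4.61 ± 0.21), HXT4 (-4.57 ± 0.32), RDN5-1, for 5S ribosomal RNA (-4.37 ± 0.40), HEM13, of heme synthesis (-4.28 ± 0.18), and YCH1 (-4.18 ± 0.12). So were TPO2 (-4.17 ± 0.24), YHB1 (-4.13 ± 0.19), RLI1, of ribosome recycling (-4.12 ± 0.14), RPL13A (-4.11 ± 0.17) and CYC7, a cytochrome c gene (-4.08 ± 0.22). RDN5-1, HEM13 and YCH1 lay near the floor at 360 min (4.45, 4.64 and 4.77), so the added value sets their sizes: -6.59, -5.73 and -5.44 with 1% of the median added and -2.49, -2.54 and -2.52 with 50%.

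In total 1826 probe sets were higher and 1987 lower (47.9% higher), against 1656 and 2235 as deposited (42.6%), 2092 and 1803 with median-centred arrays (53.7%), and 1005 and 1753 over nuclear protein-coding genes (36.4%). Adjusted over the list alone the counts in these lists were the same. The difference of ACT1 was 3.28 above that of control cells (adjusted p = 1.57e-15). With the deposited scaling 5 of the 11 list calls held and with median-centred arrays 7, those of fatty acid oxidation, translation factors, ergosterol and amino acid synthesis under both. Lists that missed the threshold under both had medians of 4.25 and 4.49 (gluconeogenesis), 1.49 and 1.72 (stationary phase) and -1.54 and -1.30 (respiratory chain), with adjusted p from 0.059 to 0.256. As deposited the mitochondrial ribosome (-1.30), ribosome biogenesis (-0.90) and the proteasome (-1.10) missed it too, and when centred autophagy (1.01).

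**Figure D5:**
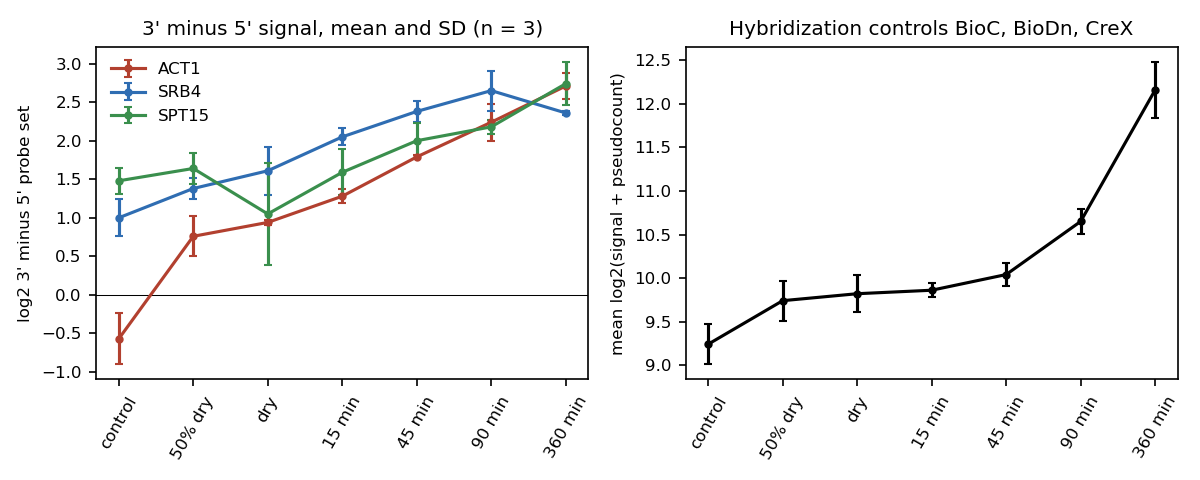
Left, 3' minus 5' log2 signal of ACT1, SRB4 and SPT15 by group; right, mean log2 signal of 6 probe sets of spiked hybridization controls by group; means and SDs of 3 arrays. ACT1 went from -0.57 to 2.71 and the hybridization controls from 9.24 to 12.16.

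Among the genes with deletions in the strain, URA3 read 2.77 ± 1.40 (SD) in control cells and 1.17 to 2.60 in the other groups. These signals lay at the 2.1 to 4 percentile of the tested probe sets. The brightest LEU2 probe set read 90.8 ± 16.2 in control cells and 22.1 ± 5.67 in dry cells. It was called lower in dry cells and at 360 min, each against control cells, so a dim set of a gene with a deletion can pass the calling rule. With 50% of the median added both changes were less than 2-fold (-0.74 and -0.76). The brightest HIS3 probe set read 837 ± 34.8 in control cells, 139 ± 8.10 in dry cells and 268 ± 30.0 at 360 min, and the part of the gene its probes cover is not given in the sources used here, so it says nothing on background. Neither list of markers of other cell states passed its test in these comparisons: of 26 meiosis and sporulation genes, 7 rose, none fell and 19 did neither in dry against control cells (median 0.78), and of 19 haploid-specific genes 2 rose, 3 fell and 14 did neither (median 0.00).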

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

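The splits of arrays were planned before any result was seen, and the 8 tests of patterns given here were all chosen after results were seen.

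Probe sets outside the comparisons rose above their level on the control arrays, which is what marked them. The array type carries several control sets for 25S ribosomal RNA. Set a averaged 346 in control cells (highest control array 672.2), 2389 in dry cells, 4530 at 45 min, 3902 at 90 min and 11994 at 360 min. Set e also averaged 346 in control cells (highest 798), with 3437 in dry cells, 2951 at 15 min and 2308 at 360 min.

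Spiked hybridization controls, which are added after the yeast RNA is labelled, were marked at 360 min. BioB-3 averaged 353 there against 70.7 in control cells, BioB-M 321 against 48.4, BioC-3 2570 against 288 and BioC-5 2438 against 423. BioDn-3 averaged 10011 against 1391, BioDn-5 1747 against 159, CreX-3 10163 against 1375 and CreX-5 8851 against 1106.

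The first pattern concerned 28 probe sets that were bright in other groups but varied strongly among the control arrays, 22 of them called higher and 0 lower in 50% dry cells. It was not confined to control arrays. By the same limits 15 probe sets varied so among 50% dry arrays, 9 among dry arrays, 10 at 15 min, 3 at 45 min, 4 at 90 min and 3 at 360 min. The SSA1 set averaged 48 in 50% dry cells, 0 in dry cells and 6 at 90 min, against 12195 at 360 min. The HOR7 set averaged 53 in dry cells and 65 at 45 min, against 17042 at 360 min. On the first control array 8 of the 28, of ENO1, ENO2, TDH3, RPS26A, RPP1B, RPL21A and YDR524C-B (2 probe sets), read 137.8 or 137.9, while 100 draws of as many probe sets in the range of 100 to 200 gave at most 4 that shared a value with another gene. The sharing cannot tell a signal lost or fixed on the control arrays from transcripts scarce in growing cells. It was seen first and, in that range, occurred on 1 array only, with 0 and 0 such probe sets on the other 2. Below that range TDH3, RPS26A and RPL21A all read 0 on the second control array. Another probe set of RPP1B alone averaged 4807 on the control arrays against 121. These values argue against scarce transcripts for RPP1B. A set annotated to RPS26A alone averaged 3717 against 46, but it is of the f type, which can read related genes such as RPS26B. Sets shared by ENO1 and ENO2 and by TDH3 and TDH2 averaged 2738 and 5498, so these genes stay open, as do RPS26A, RPL21A and YDR524C-B. Another set of YDR524C-B read 2600.7, 4321.4 and 364.2 on the control arrays, but it was itself among the 28. For the other 20 the explanations cannot be told apart. For 7 of them another probe set of the gene read a median of 4.76 times as much on control arrays, at a median percentile of 97.2. But only 3 of these have one of that gene alone. No other biological explanation was tested.

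The second pattern was a rise of small nucleolar RNA, tRNA and transcripts of the mitochondrial genome at 360 min against dry cells, such as SNR17A and COB, while ribosomal RNA probe sets had a median of -0.03. Less labelled yeast RNA on the 360 min arrays predicts a rise of the hybridization controls, and the smallest rise among their 6 probe sets was 1.83 on the log2 scale, so this explanation remained open. For RNA fragmentation, the 3' minus 5' difference rose in each transcript read, by 1.77 ± 0.18 for ACT1, 1.69 ± 0.23 for SPT15 and 0.75 ± 0.17 for SRB4. The test used the smaller of the changes of SRB4 and SPT15. At 0.75 it fell short of the rise set for fragmentation but was too large to exclude it, so the test did not decide. For the rise of tRNA and small nuclear RNA in dry against 50% dry cells, less labelled RNA was excluded, since the hybridization controls moved by a median of 0.1. No biological explanation was tested.

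The third pattern was the small number of probe sets called in each step from dry cells to 90 min (11, 7 and 16). Wider spread among these arrays was excluded, as the ratio of their median within-group SD to that of the other groups was 0.947. In simulated data 84 to 92% of 3-fold changes were called in these 3 comparisons, and 46 to 48% of 2-fold changes. The fold minimum limits the latter share: 74 to 84% of 2-fold changes passed the adjusted p in the right direction. The simulation held 50 changes of each size, more than were called in these steps, so it does not show the power where few genes change. No biological explanation was tested.

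In each comparison 1 of the 10 splits of the 6 arrays, the real one, reached its own count, and 10 splits are too few for a share under 0.05. The real and the highest other count of probe sets were 2499 and 1 for 50% dry against control, 752 and 1 for dry against 50% dry, 3245 and 0 for dry against control, 11 and 0 for 15 min against dry, 7 and 0 for 45 against 15 min, 16 and 0 for 90 against 45 min, 639 and 8 for 360 against 90 min, 2147 and 6 for 360 min against dry, and 3813 and 1 for 360 min against control. For lists the highest other count was 3 in 360 against 90 min (6 in the real one) and 0 elsewhere. Of 100 groupings of the arrays into 7 groups, 1, the real one, had as many as 7652 probe sets by the F test, and the next highest had 3725.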

How the results depend on the processing

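All alternatives were planned before results were seen, except that the tests with the hybridization run block, without unsteady probe sets, without the 360 min group and over nuclear protein-coding genes were chosen after. The F test gave 7338 to 8217 probe sets, and 6887 with the dim filter. Of 471 named gene results none reversed under the alternatives run on them, which did not include the dim filter, the removal of unsteady probe sets or the count over nuclear protein-coding genes; the run block covered 46. Those that left the threshold numbered 3 with 1% of the median added, 29 with 50%, 7 as deposited, 13 with centred arrays, 4 with only the arrays compared and 40 of 2826 with an array left out. Of 118 list results described, 38 were weaker as deposited, 36 with centred arrays, 7 of 18 with the run block, 5 of 18 in its 4 groups without the block, and 39 of 708 with an array left out; the lists that passed numbered 62 in all comparisons, 24 as deposited and 26 with centred arrays. The cause of these differences was not tested.

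With 1% of the median added, 90 against 45 min gave 35 called probe sets and 360 against 90 min 1042. With 50% added, dry against 50% dry gave 410, 15 min against dry 7, 45 against 15 min 4, 90 against 45 min 3, 360 against 90 min 265, 360 min against dry 1249, and 257 genes reversed. As deposited, 15 min against dry gave 18, and centred, 360 against 90 min gave 1006. Without a fold minimum the 9 counts, in the order of the report with 360 against 90 min before 360 min against dry, were 5322, 3258, 5969, 72, 95, 436, 3737, 5460 and 6562, and 1781 genes reversed, since small changes then count.

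For 45 against 15 min the count was 3 without the trend, 4 with the replicate block, 0 with only the arrays compared, 64 with the run block, 0 in the same 4 groups without it, 4 over nuclear protein-coding genes, and 1 to 15 with an array left out. For 15 min against dry it was 2 with the run block, 4 over nuclear protein-coding genes and 6 to 11 with an array left out. For 90 against 45 min it was 8 with only the arrays compared and 12 to 30 with an array left out. Over nuclear protein-coding genes, which are fewer, 360 against 90 min gave 390 and 360 min against dry 1427. With an array left out, 50% dry against control gave 2501 to 2530, dry against 50% dry 750 to 793, dry against control 3211 to 3273, 360 against 90 min 620 to 798, 360 min against dry 2150 to 2289 and 360 min against control 3801 to 3867. Without the 221 unsteady probe sets these 6 gave 2435, 732, 3169, 612, 2089 and 3718.

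A block for scan day was not run, since each group lay within a day. Replicate numbers did not pair the arrays: residuals of arrays with the same number correlated at -0.24 to 0.24, and 7 of 21 arrays correlated best with their own number. Signals near background limit the dim probe sets, where the added value sets the size of a change.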

Other observations

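The tests of RNA classes were chosen after results had been seen. At 360 min against dry cells, 54 of 59 small nucleolar RNA probe sets rose and none fell (median 1.78, limma camera adjusted p = 0.000727 with an estimated correlation, 3 arrays per group). Of 28 probe sets of the mitochondrial genome 21 rose (median 1.88, adjusted p = 0.00406), of 92 tRNA probe sets 64 rose (median 1.53, adjusted p = 0.0463), and of 4 of small nuclear RNA 2 rose (median 1.31, adjusted p = 0.026). Of 6 ribosomal RNA probe sets 2 rose and 1 fell (median -0.03, adjusted p = 0.942), and of 7 of other RNA genes none rose and 1 fell (median 0.13, adjusted p = 0.909). Of 6291 probe sets of nuclear protein-coding genes 414 rose and 1013 fell (median -0.20, adjusted p = 4.88e-10), and of 2443 without a gene name 441 rose and 60 fell (median 0.28, adjusted p = 2.43e-07). The spiked hybridization controls stood at 7.58-fold of control cells at 360 min and at 1.5-fold in dry cells.

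In dry against 50% dry cells, 72 of 92 tRNA probe sets rose and none fell (median 1.78, adjusted p = 0.0175), and all 4 of small nuclear RNA rose (median 2.69, adjusted p = 0.00536). In 50% dry against control cells, 43 of the 92 tRNA probe sets fell and 2 rose (median -0.79, adjusted p = 0.39). From 90 to 360 min, 26 of 59 small nucleolar RNA probe sets rose (median 0.93, adjusted p = 0.000826), as did 44 of 92 of tRNA (median 0.94, adjusted p = 0.028). No biological explanation was tested.

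The first principal component held 54.2% of the variance and the second 22.3%. The 20 brightest probe sets took 6.08 ± 1.05% (SD) of the signal at 360 min and 2.17 ± 0.21% in control cells.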
